A study of Homo sapiens with 8 samples.

How the data were processed

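The study measured poly(A) RNA of CHP212 neuroblastoma cells, WT or with FAM193A knocked out, treated for 12 h with Nutlin-3a at 10 uM or DMSO at 0.2%, in 8 libraries. Per the labels' protocols, RNA was extracted with TRI reagent and made into strand-specific TruSeq libraries. Replicates are independent biological replicates, per the series' design text. Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples by name. The submitters' processing notes name bcl2fastq, FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9.0, SAMtools 1.5, Picard 2.9.4 and HTSeq 0.8.0, with the GRCh37 (hg19) build. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping, antisense and near-identical genes can share or lose reads. The reference at hand was of another build and served for gene synonyms and biotypes alone.

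The authors deposited a table of whole read counts per gene, with 25369 genes and 4183 of them at 0 in all 8 libraries. They also deposited RPKM values, that is read counts scaled to gene length and library depth. For 16048 of 16048 genes checked, the deposited RPKM and count values gave a whole-number gene length in every library, within 0.001 bases. Totals were 28390405 to 38010075 reads per library. Replicate pairs differed by more than counting noise over genes, with a chi-square per gene of 2.72 in WT DMSO, 9.26 in WT Nutlin-3a, 2.38 in KO DMSO and 4.03 in KO Nutlin-3a cells. Intervals and floors cover counting error only, and a floor of 3 reads over a group was used where a group had 0 reads.

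From the counts, edgeR 4.0.16 in R 4.3.3 fitted the 4 group means over all 8 libraries, leaving 4 residual degrees of freedom, after filterByExpr (15879 genes kept, 9490 removed) and TMM scaling. The common biological coefficient of variation was 0.0424. The quasi-likelihood F test with robust estimation was applied to 5 comparisons, namely Nutlin-3a against DMSO in each genotype, KO against WT in each treatment, and the difference of the 2 responses. Adjusted p values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Log2 fold changes are the fitted ones, and CPM uses TMM-scaled totals.

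Before the data were examined, 24 gene lists were fixed, and 23 of them had at least 5 tested members. They cover p53 targets (arrest, apoptosis, feedback, repair and metabolism, and a core set), p53 network regulators, G1/S, G2/M, adrenergic, mesenchymal, neuronal, glial, ribosome biogenesis, ribosomal protein, histone, interferon, NF-kB, stress, cholesterol, hypoxia, matrix and immediate early genes and markers of other lineages. The list of mitochondrially encoded genes had 0 members in the count table and was not tested. Lists were tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 23 lists of a comparison. The p53 target lists overlap, and 4 member names were matched through synonyms.

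The genes named follow a rule fixed at the same point. In every comparison it takes FAM193A, MDM2, MDM4, CDKN1A, BAX, BBC3 and MYCN. It adds up to 8 genes with the largest called rise and 8 with the largest called fall among genes with a mean log2 CPM of at least 1, no overlap between the groups compared and a symbol that is not a clone, LOC, LINC, antisense, microRNA or pseudogene name. For the interaction, every difference between KO replicates had to lie on one side of every difference between WT replicates. It also adds from each tested list up to 3 called members with the smallest p, or the member with the smallest p where none was called. Some of those were left out for length, and a few genes that the rule takes are not reported here.

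The alternatives tried were DESeq2 1.42.0 size factors and upper-quartile factors, no low-count filter, the DESeq2 Wald test, the replicate number as a block, fits of 4 libraries, limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1), other thresholds, each library left out, camera with an estimated correlation, and fry. The edgeR and camera steps were tested on simulated data of 15879 genes. There, of 100 genes changed 1.5-fold and 100 changed 2-fold, 90 and 100 were recovered for the WT response, 93 and 100 for KO against WT under Nutlin-3a, and 78 and 96 for the interaction. In the same order 18, 13 and 17 unchanged genes were called. The changed genes were drawn from those with a mean log2 CPM of at least 1, so the recovery does not cover genes with fewer reads. They were changed in WT Nutlin-3a cells alone, with all other genes alike in the 4 groups. The recovery and the calls of unchanged genes need not carry over to data with many changes.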

Results

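Poly(A) RNA was sequenced from CHP212, a human neuroblastoma cell line with high MYCN expression, in its unmodified form (WT) and after knockout of FAM193A (KO). Cells of each genotype were treated for 12 h with Nutlin-3a at 10 uM or with DMSO at 0.2%. Nutlin-3a occupies the p53-binding pocket of MDM2, the ubiquitin ligase that keeps p53 low. The 4 groups (WT DMSO, WT Nutlin-3a, KO DMSO and KO Nutlin-3a) held 2 independent biological replicates each. The labels name 1 KO population, so an effect of the lost gene cannot be told from any other property of that population. The p values for differences between genotypes measure the spread between replicates, not between KO populations. Read totals per library ran from 28390405 to 38010075, and 15879 of 25369 listed genes had enough reads to be tested. Group levels are given in CPM, read counts scaled to library depth, as mean ± SD with n = 2, and fold changes are log2 values with their standard errors (SE). The first principal component, with 60.2% of the variance, separated the genotypes, and the second, with 30.4%, separated Nutlin-3a from DMSO. Replicates of every group differed by more than counting noise, so all 8 libraries were counted separately.

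FAM193A, the knocked-out gene, was still read in every KO library. Its reads in replicates 1 and 2 were 1343 and 1138 in WT DMSO, 1529 and 1238 in WT Nutlin-3a, 1244 and 1240 in KO DMSO, and 1548 and 1269 in KO Nutlin-3a. The transcript was lower in KO than in WT cells under DMSO, at 33.5 ± 1.84 against 42.0 ± 2.95 CPM (log2 fold change -0.33, SE 0.08, adjusted p = 0.000999). Under Nutlin-3a it stood at 40.1 ± 2.76 against 47.4 ± 4.17 CPM (-0.24, SE 0.07, adjusted p = 0.00827), a call that was lost without WT Nutlin-3a replicate 1 (adjusted p = 0.0722) or KO Nutlin-3a replicate 2 (adjusted p = 0.107). Nutlin-3a raised FAM193A in KO cells (0.26, SE 0.07, adjusted p = 0.00953), although not without KO DMSO replicate 2 (adjusted p = 0.138) or KO Nutlin-3a replicate 1 (adjusted p = 0.149). Its change in WT cells was 0.17 (SE 0.07, adjusted p = 0.0538), and passed the threshold without WT DMSO replicate 1 (adjusted p = 0.0244) or WT Nutlin-3a replicate 2 (adjusted p = 0.00282). With all 8 libraries that change also passed with DESeq2 size factors, upper-quartile factors, no low-count filter or the replicate block (adjusted p from 0.0182 to 0.0430), and not with the DESeq2 Wald test or limma-trend (adjusted p from 0.0888 to 0.171). The call under Nutlin-3a was also lost with limma-trend on each RPKM scale (adjusted p from 0.164 to 0.228), and those under DMSO and in the KO response with limma-trend on log2(RPKM + 0.1) and no low-value filter (adjusted p = 0.0529 and 0.0624). The edit itself is not described in the sources used here, and a small edit can leave the transcript level near normal, so these levels are a weak check of the genotype labels.

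**Figure D1:**
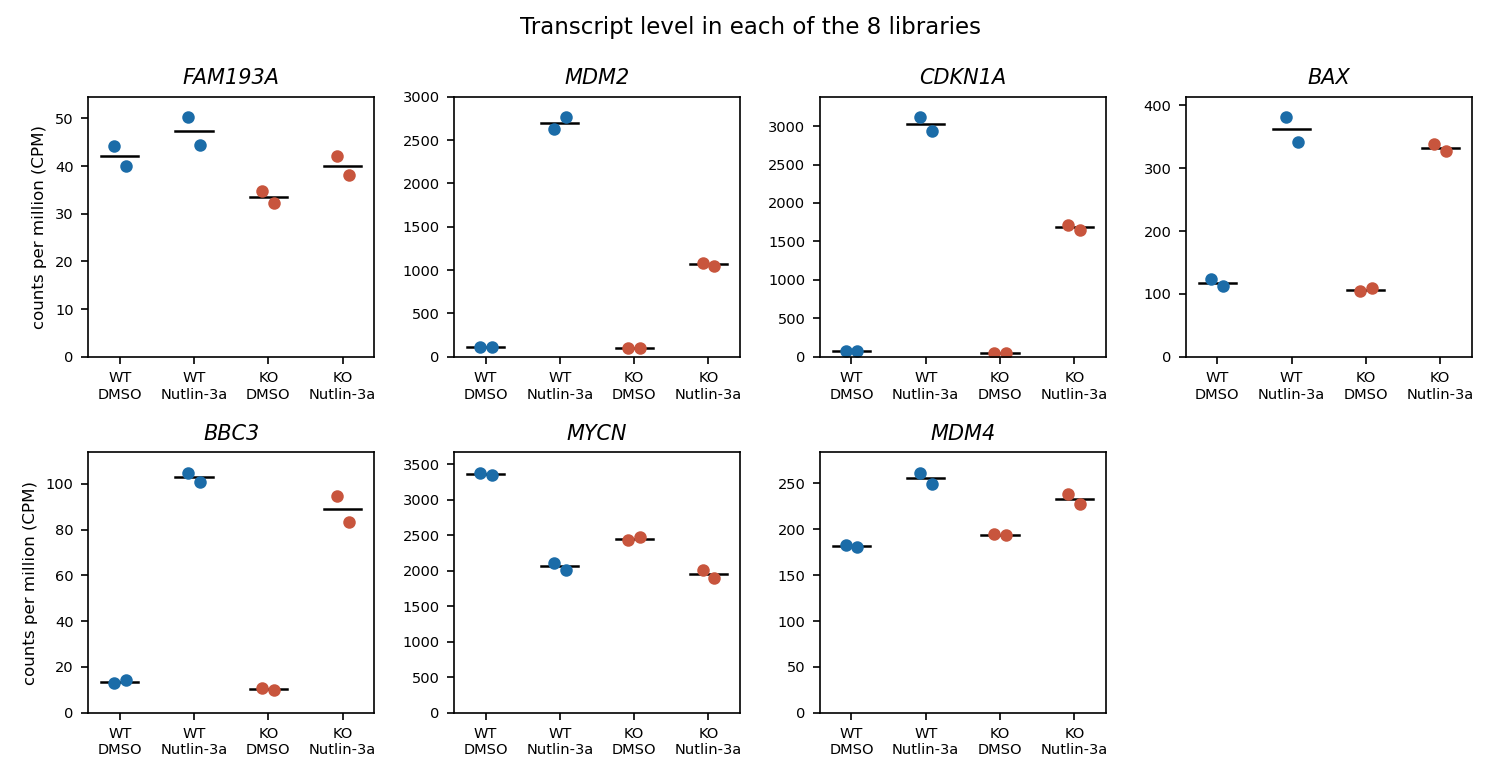
Expression of 7 genes in the 8 libraries. The vertical axes show CPM, starting at 0, each dot is a library (blue for WT, red for KO), and each black line is the mean of the 2 replicates of a group. MDM2 reached 2697 CPM in WT and 1066 CPM in KO cells under Nutlin-3a from about the same level under DMSO (111 and 103 CPM), whereas BAX ended at 362 and 333 CPM.

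The comparison of WT cells with and without Nutlin-3a asks what MDM2 inhibition does to transcription in the unmodified line. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 72.4 ± 0.80 to 3032 ± 131 CPM (log2 fold change 5.39, SE 0.06, adjusted p = 4.1e-21). MDM2 itself rose from 111 ± 3.15 to 2697 ± 106 CPM (4.61, SE 0.06, adjusted p = 7.4e-21). The pro-apoptotic genes BBC3 (2.94, SE 0.08) and BAX (1.62, SE 0.06) rose as well. MYCN, the amplified oncogene of many neuroblastomas, fell from 3365 ± 24.2 to 2059 ± 69.1 CPM (-0.71, SE 0.05, adjusted p = 3.4e-10). MDM4, the gene for the MDM2 partner, rose by 0.49 (SE 0.05, adjusted p = 3.2e-08).

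Of 87 core p53 targets measured in WT cells, 86 rose and 0 fell with Nutlin-3a, with a median log2 fold change of 1.97. Adjusted over the list alone, the counts of this and of the other lists called in this comparison were the same. The list stood apart from other genes (adjusted p = 2.6e-33 by camera). Among targets with roles in apoptosis 20 of 21 rose, among them FDXR (4.79, SE 0.06), TP53I3 (4.71, SE 0.06) and TP53INP1 (4.49, SE 0.06), with adjusted p = 4.2e-11 for the list. Arrest targets rose in 9 of 10 cases and fell in 1, as for ZMAT3 (2.60, SE 0.05) and GADD45A (2.63, SE 0.05), with adjusted p = 3.2e-05. Repair and metabolism targets rose in 20 of 23 cases and fell in 1, as for the ribonucleotide reductase subunit RRM2B (3.10, SE 0.05), with adjusted p = 2.7e-11. Feedback regulators of p53 rose in 6 of 9 cases and fell in 1 (adjusted p = 0.00116, and adjusted p = 0.117 with an estimated correlation). The largest rises of single genes included PDE4C, a cAMP phosphodiesterase, from 0.186 ± 0.02 to 289 ± 18.0 CPM, and CATSPERD, which had 0 reads under DMSO. Set against a floor of 3 reads over the group, CATSPERD was 423-fold higher under Nutlin-3a. The lower limit of the counting interval of its rise was 343-fold.

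Cell cycle genes went the other way in WT cells. Of 40 G1/S genes 39 fell and 0 rose (median -2.47, adjusted p = 4.9e-22), and all 40 G2/M genes fell (median -1.50, adjusted p = 5.9e-20, and adjusted p = 0.117 with an estimated correlation). The replication licensing factor MCM4 fell from 359 ± 5.46 to 39.7 ± 1.99 CPM (-3.18, SE 0.05), RRM2 fell by 3.09 (SE 0.05), and the transcription factor E2F1 fell by 3.78 (SE 0.07). CCNE2, the gene for cyclin E2, had the largest fall of those named, from 29.3 ± 0.89 to 0.497 ± 0.04 CPM (-5.87, SE 0.15). FAM111B (-4.49, SE 0.22) and MYB (-4.49, SE 0.21) fell as well. Among G2/M genes, CCNA2 fell by 2.09 (SE 0.05) and BIRC5, the gene for survivin, fell by 1.89 (SE 0.05).

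Biosynthetic genes fell too in WT cells, with 18 of 23 cholesterol synthesis genes lower and 3 higher (adjusted p = 1.4e-05, and adjusted p = 0.117 with an estimated correlation), such as HMGCS1 (-1.37, SE 0.04) and ACAT2 (-1.54, SE 0.05). Of 30 ribosome biogenesis genes 22 fell and 3 rose (adjusted p = 5.2e-05, and adjusted p = 0.165 with an estimated correlation), as for NOP56 (-0.79, SE 0.05). Ribosomal protein genes rose in 28 of 32 cases (adjusted p = 4.0e-06, and adjusted p = 0.478 with an estimated correlation), as for RPS19 (0.83, SE 0.05). Immediate early genes rose in 12 of 19 cases and fell in 1 (adjusted p = 0.00413, and adjusted p = 0.437 with an estimated correlation), including the stress-induced factor ATF3 (1.89, SE 0.12). Another member, MYC, chosen after its values were seen, had 37 reads in WT Nutlin-3a replicate 1 and 4 in replicate 2. Unfolded protein and amino acid stress genes rose in 16 of 25 cases and fell in 4 (adjusted p = 0.00329, and adjusted p = 0.322 with an estimated correlation), as for the mTOR inhibitor DDIT4 (1.58, SE 0.06). Histone genes rose in 7 of 13 cases (adjusted p = 0.0115, and adjusted p = 0.117 with an estimated correlation), as for HIST3H2A (1.61, SE 0.10), although poly(A) selection captures few histone transcripts and histone copies can share reads. Adrenergic neuroblastoma genes fell in 12 of 25 cases and rose in 2 (adjusted p = 0.0126, and adjusted p = 0.165 with an estimated correlation), including TH, the gene for tyrosine hydroxylase (-1.02, SE 0.05). Its member ALK, chosen after its values were seen, had 157 reads in WT Nutlin-3a replicate 1 and 4 in replicate 2.

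In all, 4673 genes were higher and 4634 lower in WT cells after Nutlin-3a, of which 1318 and 916 changed by more than 2-fold. Of 23 lists, 14 were called with the preset correlation of 0.01, and 5 of those (core, arrest, apoptosis and repair targets and G1/S genes) held with an estimated correlation, at adjusted p from 0.0303 to 0.0465. The 7 histone genes became 4 when WT DMSO replicate 2, WT Nutlin-3a replicate 1 and KO Nutlin-3a replicate 2, which carried reads of unrelated genes, were left out together. The mesenchymal genes were not called as a list (13 of 29 higher, 9 lower, adjusted p = 0.370), although CTGF (1.34, SE 0.06) rose. The smooth muscle actin gene ACTA2 (4.33, SE 0.10) and the neurofilament gene NEFL (2.00, SE 0.06) rose as well.

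The comparison of KO cells with and without Nutlin-3a asks whether the cells labeled KO still answer MDM2 inhibition. CDKN1A rose from 48.3 ± 0.32 to 1683 ± 41.6 CPM (5.12, SE 0.06, adjusted p = 9.1e-21) and MDM2 from 103 ± 0.82 to 1066 ± 21.6 CPM (3.38, SE 0.05, adjusted p = 7.0e-19). BBC3 (3.10, SE 0.08), BAX (1.64, SE 0.06) and MDM4 (0.27, SE 0.05) rose, and MYCN (-0.33, SE 0.05) fell. PDE4C rose from 0.663 ± 0.38 to 136 ± 3.93 CPM. Of the 87 core p53 targets 82 rose and 0 fell (median 1.55, adjusted p = 6.6e-46), with the same count adjusted over the list alone.

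The p53 target lists moved together in KO cells too. Apoptosis targets rose in 18 of 21 cases (adjusted p = 2.6e-16), as for FDXR (4.34, SE 0.06), TP53I3 (2.75, SE 0.05) and the death receptor gene TNFRSF10B (2.41, SE 0.05). Arrest targets rose in 8 of 10 cases and fell in 1 (adjusted p = 2.4e-07), as for ZMAT3 (2.22, SE 0.05) and GADD45A (1.96, SE 0.05). Repair and metabolism targets rose in 18 of 23 cases (adjusted p = 2.4e-14), as for C12orf5 (2.32, SE 0.05), the older symbol of the glycolysis regulator TIGAR. Feedback regulators rose in 6 of 9 cases (adjusted p = 2.0e-05, and adjusted p = 0.0596 with an estimated correlation), including TP53INP1 (2.47, SE 0.05).

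G1/S genes fell in 37 of 40 cases and rose in 2 (median -1.28, adjusted p = 3.8e-24), and G2/M genes fell in 40 of 40 (median -0.86, adjusted p = 2.7e-23, and adjusted p = 0.119 with an estimated correlation) in KO cells. Falls included E2F1 (-1.96, SE 0.06), E2F2 (-2.29, SE 0.13), E2F8 (-2.92, SE 0.23), MYBL2 (-2.27, SE 0.06), ATAD2 (-2.15, SE 0.06), CDC6 (-2.10, SE 0.06), RRM2 (-1.79, SE 0.05), BIRC5 (-1.09, SE 0.04) and CCNA2 (-1.05, SE 0.05). Cholesterol synthesis genes fell in 14 of 23 cases and rose in 3 (adjusted p = 8.9e-05, and adjusted p = 0.144 with an estimated correlation), as for ACAT2 (-0.95, SE 0.05). Stress genes rose in 16 of 25 cases and fell in 1 (adjusted p = 1.8e-05, and adjusted p = 0.186 with an estimated correlation), as for the cystine transporter gene SLC7A11 (0.86, SE 0.06) and ATF3 (1.35, SE 0.11). Immediate early genes rose in 15 of 19 cases and fell in 1 (adjusted p = 5.7e-06, and adjusted p = 0.204 with an estimated correlation). Ribosome biogenesis genes fell in 14 of 30 cases and rose in 2 (adjusted p = 0.0383, and adjusted p = 0.413 with an estimated correlation). Ribosomal protein genes rose in 6 of 32 (adjusted p = 0.0129, and adjusted p = 0.682 with an estimated correlation). NEFL (2.86, SE 0.08) and the cytokine gene LIF (2.31, SE 0.11) rose as single genes.

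Nutlin-3a left 2868 genes higher and 3273 lower in KO cells, of which 676 and 232 changed by more than 2-fold. The balance turned to 3211 higher and 2812 lower with upper-quartile factors and to 2879 and 2466 with limma-trend on log2(RPKM + 0.1). The WT and KO responses share no library, and 2353 genes rose in both where independent responses would give 844, 2715 fell in both against 955, and 130 went opposite ways against 1800. Of 12 lists called, the 4 target lists (core, arrest, apoptosis and repair) and the G1/S genes held with an estimated correlation, at adjusted p from 0.0164 to 0.0360. Adjusted over the list alone, 9 arrest targets and 16 immediate early genes rose, and 1 repair target, 2 stress and 15 cholesterol genes fell, with the other counts of called lists as given. The 6 ribosomal protein genes became 18 without the 3 libraries that carried reads of unrelated genes.

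The comparison of KO with WT cells under DMSO asks how the genotypes differ before p53 is activated. TH fell from 479 ± 2.54 CPM in WT to 10.3 ± 0.83 CPM in KO cells (-5.54, SE 0.06, adjusted p = 8.7e-21). CHGA, the gene for the secretory granule protein chromogranin A, stood at 0.458 ± 0.00255 CPM in WT and 31.6 ± 0.68 CPM in KO cells (6.10, SE 0.19). CDKN2A, which encodes p16 and the MDM2 inhibitor p14ARF, stood at 0.580 ± 0.12 CPM in WT and 29.7 ± 1.22 CPM in KO cells (5.68, SE 0.15, adjusted p = 2.9e-16). The chemotactic receptor gene GPR183 fell from 114 ± 2.60 to 0.161 ± 0.03 CPM (-9.43, SE 0.15).

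Core p53 targets were higher in KO cells in 26 and lower in 36 of 87 cases under DMSO, and as a list did not stand apart (median -0.10, adjusted p = 0.450). BTG2 (1.99, SE 0.09), TP53INP1 (1.44, SE 0.06) and TP53I3 (0.89, SE 0.05) were higher in KO cells, whereas PERP (-1.94, SE 0.08), TNFRSF10B (-0.88, SE 0.05) and the growth factor gene TGFA (-5.15, SE 0.12) were lower. Apoptosis targets were lower in 12 and higher in 3 of 21 cases (adjusted p = 0.0371, and adjusted p = 0.467 with an estimated correlation). CDKN1A was lower by -0.58 (SE 0.05, adjusted p = 3.0e-08), BBC3 by -0.37 (SE 0.09, adjusted p = 0.00195) and MYCN by -0.46 (SE 0.05, adjusted p = 1.6e-07). BAX differed by -0.14 (SE 0.06, adjusted p = 0.0440), and lost its call with upper-quartile factors and in every limma-trend setting (adjusted p from 0.117 to 0.404). The BAX call was lost too without WT DMSO replicate 1 or any KO library, where the difference ran from -0.18 to -0.07. MDM2 differed by -0.11 (SE 0.05, adjusted p = 0.0674) and MDM4 by 0.09 (SE 0.05, adjusted p = 0.0986). MDM2 passed with DESeq2 size factors, the DESeq2 Wald test or the fit of 4 libraries (adjusted p from 0.0109 to 0.027). MDM4 passed with upper-quartile factors, the fit of 4 libraries or limma-trend (adjusted p from 0.0168 to 0.0273). Neither passed with no low-count filter or the replicate block. Both passed without either WT Nutlin-3a library, where MDM2 differed by -0.11 and MDM4 by 0.09.

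Adrenergic genes were higher in KO cells in 16 and lower in 7 of 25 cases under DMSO, a list that was not called (adjusted p = 0.0681). Mesenchymal neuroblastoma genes were lower in 20 and higher in 7 of 29 cases (median -0.38, adjusted p = 0.00153, and adjusted p = 0.467 with an estimated correlation), as for the ectonucleotidase NT5E (-2.33, SE 0.05), IRF1 (-2.09, SE 0.06) and CD44 (-1.44, SE 0.05). Among neuronal genes, NCAM1 was higher (2.04, SE 0.05) and NEFL lower (-2.74, SE 0.08) in KO cells. Cholesterol synthesis genes were lower in 21 and higher in 2 of 23 cases (adjusted p = 8.5e-07, and adjusted p = 0.467 with an estimated correlation), as for FDFT1 (-1.35, SE 0.05) and HMGCS1 (-1.19, SE 0.04). Ribosome biogenesis genes were lower in 27 and higher in 1 of 30 cases (adjusted p = 1.3e-06, and adjusted p = 0.467 with an estimated correlation), as for NOP16 (-0.72, SE 0.06) and RRP9 (-0.60, SE 0.05). Hypoxia and glycolysis genes were lower in 16 and higher in 4 of 24 cases (adjusted p = 0.00650, and adjusted p = 0.504 with an estimated correlation), as for PFKFB3 (-1.84, SE 0.05) and PFKP (-1.14, SE 0.05). NF-kB target genes were lower in 8 and higher in 0 of 14 cases (adjusted p = 0.0301, and adjusted p = 0.470 with an estimated correlation), as for BIRC3 (-2.62, SE 0.28). G1/S genes were lower in 24 and higher in 5 of 40 cases (adjusted p = 0.00967, and adjusted p = 0.533 with an estimated correlation). G2/M genes were lower in 22 and higher in 4 of 40 (adjusted p = 0.0115, and adjusted p = 0.704 with an estimated correlation). Ribosomal protein genes were higher in 23 and lower in 1 of 32 cases (adjusted p = 0.00226, and adjusted p = 0.704 with an estimated correlation), as for RPS6 (1.22, SE 0.05).

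Further differences under DMSO included the basement membrane collagens COL4A1 (-2.24, SE 0.05) and COL4A2 (-2.05, SE 0.05), both lower, and the protease inhibitor gene TIMP3 (2.02, SE 0.05), higher in KO cells. The lipid droplet gene PLIN2 (8.16, SE 0.23) and TMPRSS15 (7.79, SE 0.15) were higher, and ITGA8 (-6.82, SE 0.14), C8orf4 (-7.12, SE 0.28) and the keratin gene KRT8 (-1.33, SE 0.06) lower. Altogether 4990 genes were higher and 4782 lower in KO cells, 1569 and 1148 of them by more than 2-fold. The split moved to 5581 higher and 3889 lower with limma-trend on log2(RPKM + 0.1), and to 4712 and 5088 with DESeq2 size factors. Adjusted over the list alone, 37 core p53 targets, 21 mesenchymal and 23 G2/M genes were lower, with the other counts of called lists as given. By camera 9 lists were called with the preset correlation and 0 with an estimated one, where 2 had an unadjusted p under 0.05, and fry called 19.

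The comparison of KO with WT cells under Nutlin-3a asks where the genotypes stand once MDM2 is inhibited. MDM2 was lower in KO cells, at 1066 ± 21.6 against 2697 ± 106 CPM (-1.34, SE 0.05, adjusted p = 2.3e-14), and so was CDKN1A, at 1683 ± 41.6 against 3032 ± 131 CPM (-0.85, SE 0.05, adjusted p = 1.7e-11). Of 87 core p53 targets 66 were lower and 4 higher in KO cells (median -0.52, adjusted p = 1.4e-10, and adjusted p = 0.172 with an estimated correlation). Of 40 G1/S genes 36 were higher and 1 lower (median 0.79, adjusted p = 1.0e-09, and adjusted p = 0.172 with an estimated correlation). BBC3 was lower by -0.21 (SE 0.06, adjusted p = 0.00651) and MDM4 by -0.13 (SE 0.05, adjusted p = 0.0152). Both calls were lost without KO Nutlin-3a replicate 2, where the differences were -0.12 and -0.10. They were also lost in every limma-trend setting, at adjusted p from 0.174 to 0.261 for BBC3 and from 0.428 to 0.462 for MDM4. The MDM4 call was lost too with upper-quartile factors (adjusted p = 0.0695) and in the fit of 4 libraries (adjusted p = 0.0604). BAX differed by -0.12 (SE 0.06, adjusted p = 0.0687) and MYCN by -0.08 (SE 0.05, adjusted p = 0.170). BAX passed with DESeq2 size factors, no low-count filter or the DESeq2 Wald test (adjusted p from 0.0266 to 0.0407). It did not pass with upper-quartile factors, the replicate block, the fit of 4 libraries or limma-trend. Of all these, MYCN passed with the DESeq2 Wald test alone (adjusted p = 0.0448). Both passed too without WT Nutlin-3a replicate 2, where BAX differed by -0.20 and MYCN by -0.11.

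The lower p53 targets under Nutlin-3a included GADD45A (-0.89, SE 0.05), PERP (-2.12, SE 0.07), TP53I3 (-1.08, SE 0.05), EDA2R (-1.47, SE 0.07), RRM2B (-1.33, SE 0.04), C12orf5 (-1.05, SE 0.05) and TGFA (-3.50, SE 0.06). Arrest targets were lower in 8 and higher in 2 of 10 cases (adjusted p = 0.0251), apoptosis targets lower in 16 and higher in 1 of 21 (adjusted p = 0.000251), and repair and metabolism targets lower in 17 and higher in 0 of 23 (adjusted p = 2.5e-05). Each of those 3 lists had adjusted p = 0.172 with an estimated correlation. Higher cell cycle genes included MCM3 (1.67, SE 0.05), E2F1 (2.25, SE 0.08), CCNA2 (0.84, SE 0.05) and CDC25B (1.28, SE 0.05). G2/M genes were higher in 35 and lower in 0 of 40 cases (adjusted p = 3.3e-07, and adjusted p = 0.331 with an estimated correlation).

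Under Nutlin-3a TH was lower (-4.23, SE 0.06) and PHOX2A (2.70, SE 0.08) and CDKN2A (4.69, SE 0.13) were higher in KO cells. Adrenergic genes were higher in 17 and lower in 5 of 25 cases (adjusted p = 0.00908, and adjusted p = 0.172 with an estimated correlation), the list that holds ALK with its 157 and 4 reads in the WT Nutlin-3a replicates. Mesenchymal genes were lower in 21 and higher in 2 of 29 cases (adjusted p = 3.9e-05, and adjusted p = 0.172 with an estimated correlation), as for NT5E (-2.42, SE 0.05). VIP, the gene for vasoactive intestinal peptide, stood at 1096 ± 68.1 CPM in KO and 7.48 ± 0.47 CPM in WT cells (7.19, SE 0.08). FAM19A5 (7.35, SE 0.14) and TMPRSS15 (7.26, SE 0.13) were higher, and GPR183 (-9.03, SE 0.14), ITGA8 (-6.95, SE 0.15) and SBK3 (-7.24, SE 0.22) lower. The glucose transporter SLC2A1 (-2.08, SE 0.07), the chaperone HSPA5 (-0.86, SE 0.04) and the matrix proteoglycan LUM (-1.98, SE 0.06) were lower, and the serine synthesis enzyme PHGDH (1.28, SE 0.05) higher. Cholesterol genes were lower in 16 and higher in 4 of 23 cases (adjusted p = 0.00770), hypoxia genes lower in 16 and higher in 7 of 24 (adjusted p = 0.0251), ribosome biogenesis genes lower in 16 and higher in 3 of 30 (adjusted p = 0.0179), and histone genes lower in 8 and higher in 0 of 13 (adjusted p = 0.0251). With an estimated correlation these stood at adjusted p = 0.280, 0.368, 0.368 and 0.172.

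Under Nutlin-3a 5190 genes were higher and 4822 lower in KO cells, 1604 and 1348 of them by more than 2-fold, and 0 of the 12 lists called by camera held with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 21. Adjusted over the list alone, 67 core targets, 18 repair targets, 1 G2/M gene and 22 mesenchymal genes were lower, and 3 mesenchymal and 5 cholesterol genes higher, with the other counts of called lists as given. The split moved to 6209 higher and 3747 lower with limma-trend on log2(RPKM + 0.1), a scale on which the median gene lay at 0.11 instead of 0.02, and turned to 4954 and 5096 with DESeq2 size factors and to 4372 and 4615 with the DESeq2 Wald test. The 8 lower histone genes became 4 without the 3 libraries that carried reads of unrelated genes. The 2 genotype comparisons share no library, and 3581 genes were higher in KO cells in both against 1631 for independent differences, 3317 lower in both against 1452, and 581 went opposite ways against 3078.

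The difference between the KO and WT responses, tested as an interaction, asks whether the KO cells answer Nutlin-3a differently from the WT cells. The rise of MDM2 was smaller in KO cells by -1.23 on the log2 scale (SE 0.07, adjusted p = 8.2e-10). Those of TP53INP1 (-2.02, SE 0.08), TP53I3 (-1.97, SE 0.07) and the antiproliferative gene BTG2 (-2.40, SE 0.12) were smaller as well, but all of these already stood higher in KO cells under DMSO. In CPM their gains in KO cells were 0.57, 0.42 and 0.61 times those in WT cells, in that order. The median was 0.54 over the 43 core targets raised at least 4-fold in WT cells, and MDM2 stood at 0.37. A gain in CPM also depends on the level under DMSO and is not a measure of the log2 response. For some members the 2 scales went opposite ways. TGFA had a gain ratio of 0.10 with a log2 difference of 1.66, and KITLG 1.28 with -1.09. CDKN1A differed by -0.27 (SE 0.07, adjusted p = 0.00942), which was lost without WT DMSO replicate 1 or KO DMSO replicate 1 (adjusted p = 0.0573 and 0.0605). The responses of BAX (0.02, SE 0.08, adjusted p = 0.871) and BBC3 (0.16, SE 0.11, adjusted p = 0.310) were not called different, which does not show that they were equal. FAM193A itself had a difference of 0.09 (SE 0.11, adjusted p = 0.590), also not called. MYCN fell less in KO cells (0.38, SE 0.07, adjusted p = 0.000376).

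Over the 87 core p53 targets the median difference in response was -0.47, with 60 members lower and 5 higher (63 and 5 adjusted over the list alone), and the list stood apart (adjusted p = 2.4e-14, and adjusted p = 0.11 with an estimated correlation). Repair and metabolism targets had 18 of 23 members lower and 2 higher (adjusted p = 1.4e-07, and adjusted p = 0.11 with an estimated correlation), including RRM2B (-1.02, SE 0.07) and the lysosomal fucosidase FUCA1 (-1.80, SE 0.16). Feedback regulators had 6 of 9 members lower (adjusted p = 0.00479), including the phosphatase PPM1D (-0.35, SE 0.06), and arrest targets 6 of 10 lower and 1 higher (adjusted p = 0.00479), including GADD45A (-0.67, SE 0.07). Both had adjusted p = 0.145 with an estimated correlation. Apoptosis targets were lower in 5 and higher in 2 of 21 cases and were not called as a list (adjusted p = 0.153), although APAF1, which drives caspase activation, responded less (-1.15, SE 0.11). MDM4 differed by -0.22 (SE 0.06, adjusted p = 0.0144). That call was lost without any of 4 libraries (WT DMSO replicate 2, both KO DMSO replicates and KO Nutlin-3a replicate 2), where the difference ran from -0.23 to -0.19. It was also lost in every limma-trend setting (adjusted p from 0.0567 to 0.0784).

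**Figure D2:**
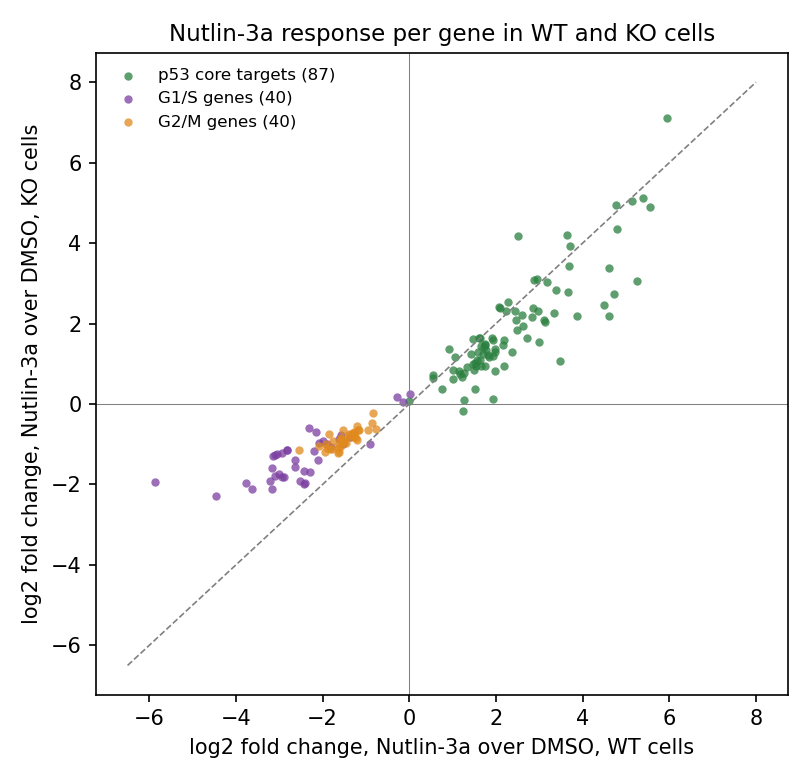
Nutlin-3a response per gene, with the log2 fold change in WT cells on the horizontal and in KO cells on the vertical axis, and a dashed line where both are equal. Each dot is a gene of the core p53 targets (87), G1/S genes (40) or G2/M genes (40). Medians of the p53 targets were 1.97 in WT and 1.55 in KO cells, those of the G1/S genes -2.47 and -1.28, and those of the G2/M genes -1.50 and -0.86.

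The fall of cell cycle genes was also smaller in KO cells. Of 40 G1/S genes 38 had a higher value in the KO response and 0 a lower one (median 1.08, adjusted p = 4.8e-25, and adjusted p = 0.11 with an estimated correlation). They included MCM3 (1.84, SE 0.07), MCM4 (1.58, SE 0.07) and the uracil glycosylase UNG (1.80, SE 0.07), and the largest upward difference named was that of CCNE2 (3.94, SE 0.21). G2/M genes had 38 of 40 members higher and 0 lower (median 0.59, adjusted p = 1.5e-18, and adjusted p = 0.145 with an estimated correlation), as for CCNA2 (1.05, SE 0.07), AURKB (1.40, SE 0.09) and FOXM1 (0.95, SE 0.07). WDR76 (2.79, SE 0.11) and MYB (2.51, SE 0.30) fell less in KO cells, and KRT17 rose less (-4.29, SE 0.38). The YAP targets CYR61 (-1.07, SE 0.09) and CTGF (-1.07, SE 0.09), ACTA2 (-2.37, SE 0.13) and TIMP3 (-1.41, SE 0.07) also rose less.

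Cholesterol synthesis genes differed in 16 of 23 cases upwards and 3 downwards (adjusted p = 9.1e-06, and adjusted p = 0.145 with an estimated correlation), as for HMGCS1 (0.87, SE 0.06) and INSIG1 (1.10, SE 0.09). Ribosome biogenesis genes differed in 17 of 30 upwards and 0 downwards (adjusted p = 1.5e-05, and adjusted p = 0.161 with an estimated correlation), as for NOP56 (0.51, SE 0.06). Ribosomal protein genes differed downwards in 17 of 32 cases (adjusted p = 7.9e-06, and adjusted p = 0.494 with an estimated correlation) and histone genes in 3 of 13 (adjusted p = 0.0425, and adjusted p = 0.161 with an estimated correlation). Adrenergic genes differed upwards in 8 and downwards in 1 of 25 (adjusted p = 0.00464, and adjusted p = 0.145 with an estimated correlation). PHGDH fell in WT cells and had a difference of 1.08 (SE 0.07). In total 2253 genes had a higher and 2120 a lower value in the KO response, 253 and 334 of them by more than 2-fold, a balance that turned to 2316 and 2453 with no low-count filter and moved to 2265 and 1580 with limma-trend on log2(RPKM + 0.1). Of the 11 lists called by camera, 0 held with an estimated correlation, where 7 had an unadjusted p under 0.05, and fry called 15. Adjusted over the list alone, 39 G1/S and 19 ribosome biogenesis genes were higher and 20 ribosomal protein genes lower, with the other counts of called lists as given.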

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

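The tests of a non-responding share of cells, of the KO population and of the starting level as the whole cause were chosen after the result was seen; that of the starting level over 47 core targets was written down beforehand. Each result listed here differed between the genotypes by the test of the interaction itself. Values are log2 differences in the Nutlin-3a response, KO minus WT, with medians over members for lists.

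Rises were smaller in KO cells for MDM2 (-1.23), MDM4 (-0.22), CDKN1A (-0.27), BTG2 (-2.40), GADD45A (-0.67), TP53I3 (-1.97), TP53INP1 (-2.02), APAF1 (-1.15), PPM1D (-0.35), RRM2B (-1.02), FUCA1 (-1.80), KRT17 (-4.29), CYR61 (-1.07), CTGF (-1.07), ACTA2 (-2.37) and TIMP3 (-1.41). Of those compared under DMSO above, BTG2, TP53I3, TP53INP1 and TIMP3 already stood higher in KO cells and CDKN1A lower, and MDM2 and MDM4 were not called in the main fit. The others need not have started at the same level in both genotypes. The calls of MDM4 and CDKN1A were lost under some alternatives, as given above. Falls were smaller in KO cells for MYCN (0.38), CCNE2 (3.94), WDR76 (2.79), MYB (2.51), MCM3 (1.84), MCM4 (1.58), UNG (1.80), CCNA2 (1.05), AURKB (1.40), FOXM1 (0.95), NOP56 (0.51), HMGCS1 (0.87), INSIG1 (1.10) and PHGDH (1.08). List medians were -0.30 for arrest, -0.33 for feedback, -0.55 for repair and metabolism and -0.47 for core p53 targets. They were 1.08 for G1/S, 0.59 for G2/M, 0.17 for adrenergic, 0.23 for ribosome biogenesis, 0.42 for cholesterol, -0.62 for histone and -0.23 for ribosomal protein genes. With an estimated correlation 0 of these 11 lists held, at adjusted p of 0.11 or more.

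The smaller response of the p53 targets in KO cells is the pattern weighed here. A higher starting level as the whole cause would let both genotypes end alike. Under Nutlin-3a, however, the 87 core targets had a median of -0.52 in KO against WT cells (bootstrap interval over genes -0.66 to -0.41), after -0.10 under DMSO. As part of the cause a higher starting level stays open. The 47 targets at or below their WT level under DMSO had a median difference of -0.26 (-0.38 to 0.02). That test cannot decide, because the DMSO level that picked these targets is also subtracted in their difference, which by itself moves the median upwards. Both intervals resample genes and leave out the variation between replicates. A share of KO cells that does not respond, as the only cause, would scale every gain in CPM alike. Over the 43 targets raised at least 4-fold in WT cells, however, the KO gain over the WT gain ran from 0.0800 to 1.28. Its quartile ratio of 1.57 (1.36 to 2.16) did not by itself clear the bound of 1.5. A test of the spread, added later, gave 64.7 times the variance that the error of the fit gives (27.7 times over the 12 not called different under DMSO). The genotypes differed in 9772 of 15879 genes under DMSO, so unequal gains could be foreseen. The spread therefore bears on such a share as the only cause, and cannot weigh it as part of the cause. The labels name 1 KO population, so the lost gene and any other property of that population cannot be told apart. A reduced p53 output without FAM193A may be the biological reading, a hypothesis that further KO populations or re-expressed FAM193A would test and that was not tested here, with a starting level or a non-responding share as part of the cause open too.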

How the results depend on the processing

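The fit without 3 libraries, the upper-quartile value of the p53 median, and the list counts and list medians under other settings were chosen after seeing the data; the other alternatives were set before. Of 3121 values of the named genes under the alternatives 3039 kept direction and side of the threshold, 54 lost and 28 gained the call, and 0 reversed. Most of these genes were named for large changes or small p in the same libraries, so few changes could be foreseen. The share therefore does not carry over to other genes. Apart from PPM1D and NOP56 under the 1.5-fold requirement, all changed calls fell on the genes taken in every comparison. Leaving out single libraries, with the lone replicate assumed to vary like the other groups, gave 3864 to 4829 genes higher and 3840 to 4582 lower for the WT response, 1922 to 3660 and 2289 to 3934 for the KO response, 4189 to 5382 and 3983 to 5217 for KO against WT under DMSO, 4425 to 5097 and 4116 to 4869 under Nutlin-3a, and 1600 to 2613 and 1459 to 2724 for the interaction. Requiring a 1.5-fold change left 2221 higher and 1931 lower, 1154 and 664, 2503 and 1901, 2656 and 2220, and 779 and 735 in the same order, by construction. The lower count of the interaction was 1312 with limma-trend on log2(RPKM + 0.1) and no low-value filter; the cause was not tested. Lists called fell to 5, 5, 0, 0 and 0 with an estimated correlation, which 4 residual degrees of freedom estimate poorly, and fry, which does not compare a list with other genes, called 19 for KO against WT under DMSO and 21 under Nutlin-3a. The median difference over the core p53 targets of -0.47 ranged from -0.50 to -0.42 with single libraries left out and was -0.46 with either other scaling. Without the 3 libraries that carried reads of unrelated genes, with 1 residual degree of freedom left, it was -0.47, and 59 core targets were lower and 9 higher against 60 and 5. Medians of the 58 list results called kept their sign under 4 other scalings, and 8 of 57 not called changed it. Deviations of same-numbered replicates correlated at -0.10 to 0.17 over 6 pairs of groups. These gave no sign that the numbers pair the samples, but cannot exclude a weak effect shared by same-numbered replicates. The replicate block gave 4676 higher and 4647 lower for the WT response, 2887 and 3257 for the KO response, 5004 and 4828 and then 5202 and 4834 for KO against WT, and 2248 and 2112 for the interaction. In libraries simulated at this depth with 2 replicates, 78 of 100 interactions built at 1.5-fold and 96 of 100 at 2-fold were called. These were built in genes with a mean log2 CPM of at least 1, and smaller interactions were not simulated. All other simulated genes were alike in the 4 groups, whereas in the data 9772 of 15879 genes differed between the genotypes under DMSO. The recovery need not carry over.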

Other observations

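The tests of the DUX4 target set and those that compare replicate partners were chosen after the result was seen; those on the colon markers and panel genes were written down beforehand. Genes outside the naming rule are named here after their values were seen.

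Several fixed lists moved in parts without standing apart as lists in any comparison. Regulators of the p53 network were higher in 7 and lower in 11 of 23 cases in the WT response and higher in 8 and lower in 7 in KO against WT cells under DMSO, with adjusted p = 0.483 and 0.746. Neuronal maturation genes were higher in 15 and lower in 9 of 27 cases in KO cells under DMSO (adjusted p = 0.450), a list whose members NTRK2 and NTRK3 each had 49 reads in WT Nutlin-3a replicate 1 and 1 and 2 in its partner. Interferon response genes were higher in 3 and lower in 7 of 23 cases in the KO response (adjusted p = 0.0584), matrix genes higher in 12 and lower in 11 of 30 in KO cells under DMSO (adjusted p = 0.992), and glial and Schwann cell genes higher in 4 and lower in 6 of 11 (adjusted p = 0.746). Markers of other lineages were higher in 5 and lower in 5 of 16 cases in KO cells under DMSO (adjusted p = 0.992), and hold KDR with 78 reads in WT Nutlin-3a replicate 1 and 1 in its partner. Among the 57 list results not called, the median, mean and test differed in sign in 20.

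Genes that the embryonic transcription factor DUX4 is known to activate rose with Nutlin-3a in both genotypes, on a list written after a few of them had led the table of rises. Summed over 34 listed genes, the replicates stood at 5.3 and 5.2 CPM in WT DMSO, 110 and 113 in WT Nutlin-3a, 9.2 and 10.4 in KO DMSO, and 163 and 160 in KO Nutlin-3a cells. Of 24 tested members 21 rose in both genotypes, and 18 were higher and 0 lower in KO than in WT cells under DMSO. The other 3 were PANX2, which fell in WT cells (-0.56, SE 0.22, adjusted p = 0.0352) with -0.05 in KO cells (adjusted p = 0.874), TRIM48, with adjusted p = 0.0599 in KO cells, and PRAMEF2, with adjusted p = 0.268 in WT cells. PANX2 with 4.09 CPM and CCNA1 with 0.815 CPM make up most of the sum in WT DMSO cells. Many tested members had 0 reads in WT DMSO and could pass the low-count filter only through other groups. That favors a rise among the tested ones, and 5 of the 34 listed genes had 0 reads in all 8 libraries. Some differences under DMSO rest on few reads, as for TRIM49C with 4 and 4 in KO against 0 and 0 in WT cells. Others rest on more, as for KHDC1L with 29 and 38 against 3 and 0. ZSCAN4 had 1 and 1 reads in WT DMSO and 281 and 260 in WT Nutlin-3a, a ratio of 274 with a counting interval from 75.5 to 2268.

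For that DUX4 target pattern, reads shared between near-identical copies are argued against by 7 of 8 tested single-copy members that rose in both genotypes. This holds for those members, as the single-copy genes LEUTX, DUXA, KLF17 and ZIM3 had too few reads to be tested. Reads from another sample are argued against by the replicates, whose summed CPM differed at most 1.03 times within a Nutlin-3a group. DUX4 itself had 0 reads in the 8 libraries, but its repeat copies may be lost in counting, so its transcription cannot be told from another activator without a count that keeps those copies.

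Reads of unrelated genes stood in single libraries of a pair. Colon epithelium markers summed to 651 reads in WT DMSO replicate 2 and 589 in KO Nutlin-3a replicate 2 against 7 to 63 elsewhere, over 21 genes picked from these counts, and of 22 further colon markers listed before their counts were seen 18 were higher in both libraries than in each of the other 6 (3.57% by chance), with PIGR at 123 and 137 reads and CEACAM5 at 91 and 89; 0 of 27 tested colon genes were called in the WT response and 1 in the interaction. That is consistent with a trace of colon RNA or reads in those libraries, and against Nutlin-3a or genotype as its source stands a summed CPM of those 22 markers 3.67 times that of the partner (counting interval 3.10 to 4.37) in WT DMSO and 4.70 times in KO Nutlin-3a cells, a test split off after the test over all 3 libraries and all genes had given 1.36. WT Nutlin-3a replicate 1 held 2504 reads of 34 kinase, cancer and drug-metabolism genes against 71 in its equally treated partner, 32.3 times the CPM, which argues against the treatment as the source for those 34, although they were picked from these counts. Of 22 further genes listed beforehand 6 were over 2 times above every other library, between the bounds set. The 12 of those 22 with a mean under 1 CPM over the other 6 libraries summed to 1.94 times the partner (counting interval 1.61 to 2.34). They include PGR, with 87 reads against 82 in the partner, which draws the ratio towards 1. PGR also had 61 and 80 reads in the WT DMSO replicates. The ratio of 1.94 and its interval lie above the 1 that an equally treated partner predicts and under the bound of 3 set against the treatment. That interval covers counting error only, so for these genes the treatment is not supported and, by the bound, not excluded either. The rule was changed after the value was seen from one that counted any ratio under 3 for the treatment. A gene panel as the source stays open too. EPHA3, EPHA7 and PTPRD, which these cells express strongly, make up most of the reads behind the 1.36. Of 26 tested panel genes 11 were called in the WT response and 2 in the interaction.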
